A study of Drosophila melanogaster with 3 samples.

How the data were processed

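The samples were 3 biological replicates of Drosophila melanogaster embryos expressing tap-eGFP, assayed by chromatin immunoprecipitation with an anti-GFP antibody and sequencing, with library fragments of 200 to 800 bp per the labels. The embryonic age of 6 to 16 h was taken from the sample source label. The lists are in dm6 per the labels. Per the notes deposited with each sample, a peak list was made from the alignments of 1 replicate and 1 control alignment, a further list from the 3 replicates pooled, and the thresholded set from these lists by the irreproducible discovery rate (IDR). The aligner, the peak caller, their versions, the read filters and the IDR threshold are not given in the sources used here, and the control libraries were not analysed here. Each deposited list gives per peak a signal value and, by the format of the file, the −log10 of a q-value, both as the authors' peak caller gave them. The scale of the signal differed between lists (the highest was 4027 in the pooled list and 1422, 1398 and 1233 in replicates 1, 2 and 3), so signals were compared as ranks within a list. The −log10 q-values were tied at the maximum for 3243 of the 4336 thresholded peaks and served only as an alternative ranking. All 4336 thresholded peaks were found unchanged in the pooled list and were its 4336 strongest. In 8 cases an interval was listed a second time with another summit, and both were kept. Since each replicate list was filled to 30000 peaks, its length says nothing of depth. Depth is unknown, and intervals on shares of peaks cover only the sampling of peaks. Peaks were called in a fixed way on each replicate and on the pool, so the thresholded set is 1 value per peak with no error of its own. Its replicate error was taken from the 4336 strongest peaks of each replicate, as mean and SD (n = 3). A control is shared by the replicates per the notes, so sites that the control under-represents would be found in all of them.

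Genes and TSSs came from Ensembl release 115 (FlyBase release 6.54) and the sequence from the RefSeq copy of the same assembly as dm6. No peak ended beyond the length of its chromosome arm. Peaks were found on 6 chromosome arms. A summit within 500 bp of any annotated TSS was promoter-proximal and all others distal. The remaining classes were assigned in the order 5' UTR, coding exon, 3' UTR, intron, other transcript and intergenic. Class shares were compared with 1000 random placements of the summits on the same arm, outside runs of N (two-sided permutation p). Peaks of 2 replicates were shared when their summits lay within 200 bp. The alternative settings of this comparison used 200 random placements in place of 1000, so their smallest possible permutation p was 0.005. Each peak was assigned to the protein-coding gene with the nearest TSS, and the number of list genes with a peak was compared with 10000 random lists matched on the decile of the length of genome nearest to the gene's TSSs (two-sided permutation p, Benjamini-Hochberg adjusted over the 20 lists). Hexamers were searched on both strands, in 200 start positions about the summit and in the same number about the points 500 bp to each side, with an exact McNemar test across peaks. Distal and promoter-proximal peaks, and the 868 strongest and 867 weakest thresholded peaks by signal, were compared with Fisher's exact test. Peaks are the units of these tests, so their p-values describe these peaks and not the spread between embryos.

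The groups, the tests, the 20 gene lists, the rule for named genes and most alternative settings were chosen before the data were examined. The rule named tap and Poxn, the genes nearest to the 25 strongest thresholded peaks, up to 4 members of each list with the strongest peaks, and the 10 hexamers of largest ratio among those past an adjusted p of 0.05 in at least 5% of summits. An item that this rule selects is not reported here. Hexamers led by the comparison with GC-matched windows, which the rule does not cover, were added by the same rule. The lists were proneural and neurogenin-family bHLH genes, the Enhancer of split and Bearded complexes, the Notch pathway, neuroblast and ganglion mother cell factors, sensory organ development, neuronal differentiation and synapse, neuronal identity factors, axon guidance, Wnt and planar cell polarity, glia, muscle and mesoderm, endoderm with gut and fat body, trachea, blood cells, epidermis and cuticle, germ line, Hox genes, heat shock and stress, cell cycle, and ribosomal proteins, the last by the pattern of their symbols. Genes of 14 listed symbols were not matched in the annotation by symbol and were left out, BobB, BobC, Dl, nct, BarH1, BarH2, isl, Toll, hnt, sal, dys, svb, nos and Hsp67Bb. Alternatives were TSS windows of 200 and 1000 bp, the 2168 strongest thresholded peaks, peak intervals in place of summits, summit distances of 100 and 500 bp, other numbers of strongest peaks, ranking by q-value, other rules of assigning peaks to genes, unmatched random lists, summit windows of 50 and 200 bp to each side, GC-matched random windows (5 per peak, in 5% bins of GC content), and leaving out each replicate in turn, for which thresholded peaks were kept when found among the strongest of both other replicates.

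The tests were first run on simulated data. With 10% of random summits moved to a TSS, 100% of 20 runs passed the placement test, and with none moved 0% did. Of 300 random lists of 25 genes, 2.67% passed the list test at an unadjusted permutation p under 0.05. When 40% of their genes were given a peak, on top of the genes that already had one, 93% did. This large effect, without adjustment, does not give the power for smaller lists or weaker effects. A copy of 50% of peaks jittered by up to 200 bp was recovered as 50.2%. A hexamer written into 10% of random summit windows was recovered with an adjusted p of 1.16e-36, and 6 of the other 2079 hexamers also passed. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.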

Results

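Chromatin immunoprecipitation followed by sequencing was used to map where tap binds in the genome of Drosophila melanogaster embryos. The gene tap encodes a basic helix-loop-helix (bHLH) transcription factor of the neurogenin family, a family with known roles in the nervous system, and bHLH factors of this kind bind E-boxes, sequences of the form CANNTG. The embryos were whole, of mixed sex and 6 to 16 h old, and carried tap fused at its C-terminus to eGFP, which was recovered with an antibody against GFP. There was 1 group of 3 biological replicates, so the comparisons implied by the design are those of the binding sites with the rest of the genome and of the replicates with each other. The deposited lists held 30000 peaks for each replicate, 30000 peaks for the pooled replicates, and a thresholded set of 4336 peaks derived from them. The lists carry no read counts, so the sequencing depth behind each peak is unknown. Coordinates are in dm6. Signal values are the authors' own, and are used to rank peaks within a list.

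The strongest peak lay in an intron of CG11050 (FBgn0031836), at 2L from 6612406 to 6612901, with a signal of 4027 in the thresholded set, and it ranked 1.67 ± 0.577 (SD, n = 3) in the replicate lists. The next was at the promoter of Ugalt (FBgn0024994), a UDP-galactose transporter gene, at X from 2703698 to 2704073, with its summit 35 bp from the transcription start site (TSS), a signal of 3856 and a mean rank of 2.33 ± 1.15 (SD, n = 3). It was followed by a peak 1408 bp upstream of the TSS of cbt, which encodes the zinc-finger transcription factor cabut (2L from 480907 to 481277, signal 3664, mean rank 3.67 ± 1.53, SD, n = 3), and by a promoter peak of px (2R from 22514111 to 22514490, signal 3416, mean rank 4.67 ± 0.577, SD, n = 3). The peak near cbt lay outside that gene, in an annotated intron of another gene. Of the 25 strongest peaks, 19 had their summit within 500 bp of a TSS, 5 lay in introns and 1, nearest to CG13323, was intergenic. The promoter peaks included those of the Polycomb group gene ph-p (signal 3309), the mitochondrial ribosomal protein gene mRpS10 (3127), the glycolytic gene Gapdh2 (2928), the casein kinase gene gish (2321) and the chromosomal protein gene Chro (2223), and those of CG18549, CG11309, CenG1A, CG13390, CG1635, CG1888, PNPase, CG14100, CG5611, Pal1, Tcs5 and Fkbp14. The intronic ones included Lk6, a protein kinase gene (2646), Trl, which encodes GAGA factor (2407), and CG32772 (2240). Each of these 25 peaks was among the 4336 strongest of all 3 replicates. The peak of Fkbp14 was the least even, at ranks 9, 13 and 961 in replicates 1, 2 and 3.

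The tap gene itself (FBgn0015550, 3L from 17359682 to 17361811, plus strand) had 1 thresholded peak. It was intergenic, at 3L from 17364207 to 17364582, beyond the 3' end of the gene and 4713 bp from its TSS. Its signal of 247.8 placed it at rank 2172 of the 4336, and it ranked 2980, 1640 and 3640 in replicates 1, 2 and 3. The pooled list assigned tap 10 peaks, this one among them, and the lists of replicates 1, 2 and 3 assigned it 11, 12 and 14. Poxn (FBgn0003130, 2R from 15826693 to 15835055, minus strand), a paired-box gene of sensory organ development, had no thresholded peak. The pooled list assigned it 3 weaker peaks, the best at rank 7251 and 590 bp from the TSS. The list of replicate 1 had none, that of replicate 2 had 3, the best at rank 4047 and 493 bp from the TSS, and that of replicate 3 had 5, the best at rank 17779.

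Peak summits were concentrated at promoters and were nearly absent from coding exons. Within 500 bp of a TSS lay 1786 of the 4336 summits (41.2%, 95% Wilson interval 39.7 to 42.7), against 13.6% of summits placed at random on the same chromosome arms, a 3.03-fold excess. The 4336 strongest peaks of each replicate gave 43.3% ± 1.24 (SD, n = 3). Only 5 summits (0.115%, 0.0493 to 0.270) lay in coding exons outside the promoter windows, where random placement put 13.7%, and 0.738% lay in 3' UTRs, against 4.38%. The intergenic share was 16.6%, against 27.4%. Introns held 39.4% of the summits and 38.7% of random positions, a difference within the spread of the placements (permutation p = 0.34, two-sided). For promoters, coding exons, 3' UTRs and intergenic sequence no placement lay as far from the mean as the data (permutation p = 0.0010, the smallest that 1000 placements can give). Among the 25664 weaker peaks of the pooled list the promoter share was 22.5% (odds ratio 2.41 for thresholded against weaker peaks, Fisher's exact p = 2.96e-139). These weaker peaks also fell below random placement in coding exons (1.86%) and 3' UTRs (2.79%), so the shortage there was not particular to the thresholded set. Placements were not matched on GC content, so the class shares are not separated from base composition. The median distance to a TSS was 143 bp for promoter-proximal peaks and 2708 bp for the other, distal, peaks.

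**Figure D1:**
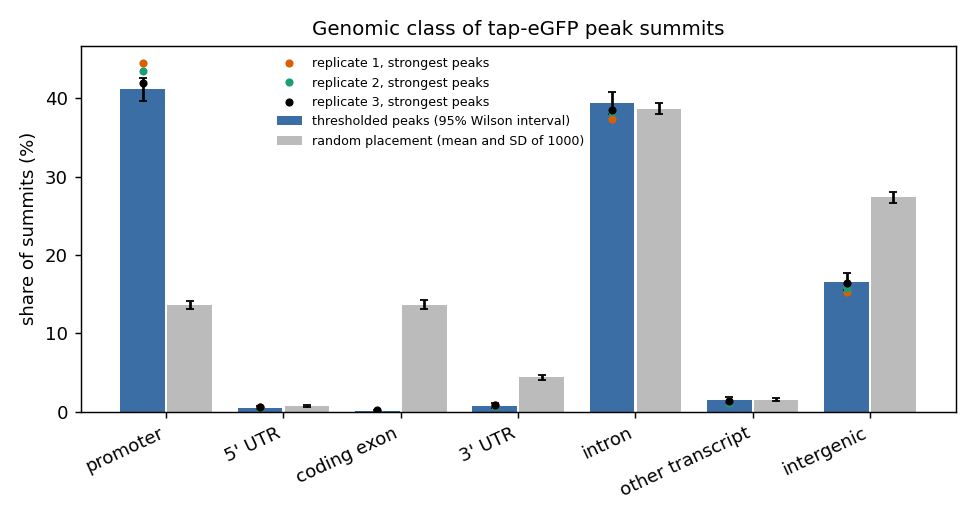
Share of peak summits (%, vertical axis) in each genomic class. Blue bars are the thresholded peaks with 95% Wilson intervals, grey bars the mean and SD of 1000 random placements, and dots the 4336 strongest peaks of each replicate. Promoters hold 41.2% of summits against 13.6% at random, and coding exons 0.115% against 13.7%.

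By chromosome arm the thresholded peaks ran from 28.8 per Mb on 2R to 35.9 per Mb on 3L, with 30.7 per Mb on X. The small chromosome 4 held 18 peaks, or 13.4 per Mb.

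The replicates shared most of their strongest sites, with replicates 1 and 2 closer to each other than to replicate 3. Of the 4336 strongest peaks of replicate 1, 73.5% had a summit within 200 bp in the corresponding peaks of replicate 2 and 58.9% in those of replicate 3. Of those of replicate 2, 57.6% were found in replicate 3. Random placement gave 1.33%. Peaks found in all 3 replicates made up 49.9%, 50% and 49.1% of the strongest peaks of replicates 1, 2 and 3 (mean 49.7%), which count nearly the same sites and so carry no replicate spread, and the random mean was 0.0165% (permutation p = 0.0010, the smallest possible, two-sided). Without replicate 3, the share common to the remaining pair was 73.7%. Of the thresholded peaks, 82.9%, 81.3% and 67.2% were among the strongest peaks of replicates 1, 2 and 3, and 2141 (49.4%) were so in all 3. In the full lists the figures were 99.0%, 99.1% and 91.7%. Across thresholded peaks, Spearman's rho of the signal was 0.76 between replicates 1 and 2 (4252 peaks), 0.54 between 1 and 3 (3936 peaks) and 0.52 between 2 and 3 (3939 peaks), a mean of 0.61 ± 0.13 (SD over the 3 pairs). Peaks are not independent replicates, so these coefficients describe the lists and carry no p-value.

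Genes of the cytoplasmic ribosome carried peaks far more often than other genes. Each peak was assigned to the protein-coding gene with the nearest TSS, which gave 2641 of 13945 genes at least 1 thresholded peak (18.9%). The strongest peaks of each replicate gave 19.3% ± 0.232 (SD, n = 3). Of 92 ribosomal protein genes, 54 had a peak (58.7%), where random lists matched on the length of genome nearest to each gene's TSS held 12.9, a ratio of 4.17. In the replicates the share was 55.8% ± 4.39 (SD, n = 3). Among the strongest of these peaks were those at RpL32 (3R from 30046145 to 30046438, signal 636.4), RpS27 (3R from 25247384 to 25247645, signal 612.7) and RpL7 (2L from 10200933 to 10201135, signal 519.7), all at promoters, with summits 21 to 99 bp from the TSS. Of the 57 peaks assigned to ribosomal protein genes, 55 were promoter-proximal. This was the only one of the 20 lists past the threshold (permutation p = 0.00020, the smallest possible, two-sided, Benjamini-Hochberg adjusted p = 0.0040 over the 20 lists).

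Lists of the nervous system, where neurogenin-family factors act, were not separable from matched random lists with peaks assigned to the nearest TSS. Among proneural and neurogenin-family bHLH genes, 5 of 15 had a peak, against 3.73 in random lists (adjusted permutation p = 0.91). These included dimm, a regulator of neuroendocrine cells (signal 313.3), Oli (306.8), da, which encodes the shared bHLH partner Daughterless (289.9, at the promoter, with no peak within 200 bp in the list of replicate 3), and tap. No thresholded peak was assigned to ac, sc, l(1)sc, ase, ato, amos or cato, also members of this list. Of the neuroblast and ganglion mother cell factors, 8 of 24 had a peak, against 8.21 (adjusted permutation p = 1.00), with brat (1086, rank 150) and grh (662.4) leading, followed by D (414.8) and insc (291.8). Of the sensory organ genes, 5 of 13 had one, against 4.63 (adjusted permutation p = 1.00), among them neur (599.0), ct (379.1), phyl (303.0) and sca (182.8). Of the genes of neuronal differentiation and synapse, 6 of 24 had one, against 7.58 (adjusted permutation p = 0.91). The pan-neuronal RNA-binding protein gene elav carried the strongest of these, at its promoter (X from 523315 to 523652, signal 1408, mean rank 81.3 ± 12.9, SD, n = 3), ahead of Syx1A (415.6), cpo (295.5) and fne (234.2). Among neuronal identity factors 9 of 20 had a peak, against 7.28 (adjusted permutation p = 0.91), led by zfh1 (771.3), zfh2 (627.5), vvl (356.0) and ftz (335.0). The peaks of vvl and ftz lay 33864 and 17475 bp from the TSS. With only peaks within 5000 bp of the TSS, 15% of this list had a peak (27.0% expected, adjusted permutation p = 0.63). Among axon guidance genes 18 of 34 had one, against 13.0 (adjusted permutation p = 0.43), led by Sema1a (588.4), Fas3 (560.4), Ptp10D (384.2) and caps (365.0). Axon guidance genes passed with gene bodies extended by 1000 bp (19 of 34, adjusted permutation p = 0.034) and, like neuronal identity factors, with unmatched random lists (adjusted permutation p = 0.0010 and 0.038).

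Lists of 2 signalling pathways and of muscle had the next smallest p-values, without passing the threshold. By ratio the order differed. Heat shock and stress genes, at 2.03, were above these 3 lists, and the Enhancer of split and Bearded complexes, at 1.96, were above the Wnt and muscle lists, both with fewer genes. In the Notch pathway 11 of 19 genes had a peak, against 5.56 (ratio 1.98, adjusted permutation p = 0.081), and the share in the replicates was 57.9% ± 5.26 (SD, n = 3). The members with the strongest peaks were numb (661.8), neur, mam (467.2, with 6 peaks) and aph-1 (339.0). Of Wnt and planar cell polarity genes, 15 of 26 had a peak, against 8.55 (ratio 1.75, adjusted permutation p = 0.081), led by the kinase gene sgg (903.4), nkd (596.0), fz (502.5) and ds (389.8). Of muscle and mesoderm genes, 14 of 25 had one, against 8.04 (ratio 1.74, adjusted permutation p = 0.089), led by tin, a heart and mesoderm homeobox gene (828.1), kirre (764.6, with 7 peaks), sls (738.3) and bin (664.4). With random lists not matched on the length of genome nearest to the TSS, 8 lists passed, including these 3. When a gene counted as bound if its body with 1000 bp on each side held a summit, 3 lists passed: ribosomal proteins, the Notch pathway and axon guidance. With the 2168 strongest peaks alone muscle and mesoderm passed (12 of 25, adjusted permutation p = 0.018), and with distal peaks alone, a setting added after seeing the data, Wnt and planar cell polarity did (14 of 26, adjusted permutation p = 0.040).

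The other lists were also within the range of random lists. In the Enhancer of split and Bearded complexes 5 of 16 genes had a peak, against 2.56 (adjusted permutation p = 0.47), led by E(spl)malpha-BFM (724.3), E(spl)m7-HLH (609.2), gro (541.5) and E(spl)m3-HLH (498.0). Among genes of other cell types in the embryo, the counts were 4 of 13 for glia (expected 3.51, with moody, pnt, Gli and loco), 7 of 13 for endoderm, gut and fat body (expected 4.15, led by bowl, fkh, Adh and GATAe), and 6 of 10 for trachea (expected 3.56, led by pyd, trh, rib and bnl). They were 2 of 14 for blood cells (expected 3.40, ush and crq), 4 of 15 for epidermis and cuticle (expected 3.94, grh, wrd, ovo and knk) and 2 of 10 for the germ line (expected 1.70, gcl and bam). Hox genes had 4 of 8 (expected 3.31, Antp, Abd-B, abd-A and Dfd), heat shock and stress genes 4 of 14 (expected 1.97, Hsp27, Hsp83, Hsp26 and Hsp22), and cell cycle genes 5 of 18 (expected 3.49, led by CycB, CycE, E2f1 and Cdk4). Adjusted p-values of these lists lay between 0.47 and 1.00. Several of the named peaks were uneven between replicates. Like that of da, the peaks of Adh, knk and gcl had no match in the list of replicate 3, and that of Abd-B had none in replicate 1. Those of loco, bam, Cdk4, CycE and Dfd ranked 23740, 20322, 18853, 14920 and 11144 in replicate 3, and that of phyl 9976 in replicate 2.

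**Figure D2:**
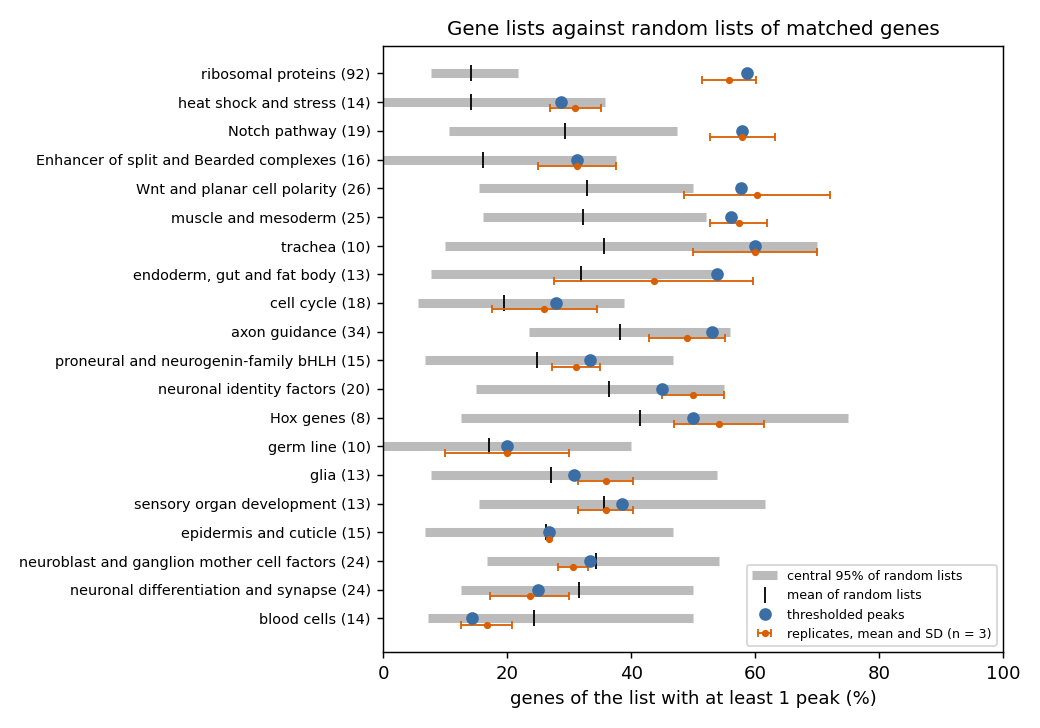
Percentage of the genes of each list (number of genes in brackets) with at least 1 assigned peak. Blue dots are the thresholded set, orange points the mean and SD of the strongest peaks of 3 replicates, grey bars the central 95% of 10000 matched random lists and black ticks their mean. Ribosomal proteins, at 58.7% against 14.1%, lie far outside the random range.

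Summits were rich in A and T. The 100 bp around thresholded summits had a mean GC content of 32.4%, and the 100 bp windows centred 500 bp to each side had 42.6%. Promoter-proximal (33.2%) and distal summits (31.9%) shared this low. The difference between summit and flanks was -10.9 and -11.2 percentage points in the strongest peaks of replicates 1 and 2, and -4.29 in replicate 3. The 868 strongest thresholded peaks had 28.7% GC at the summit and the 867 weakest 35.6%.

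**Figure D3:**
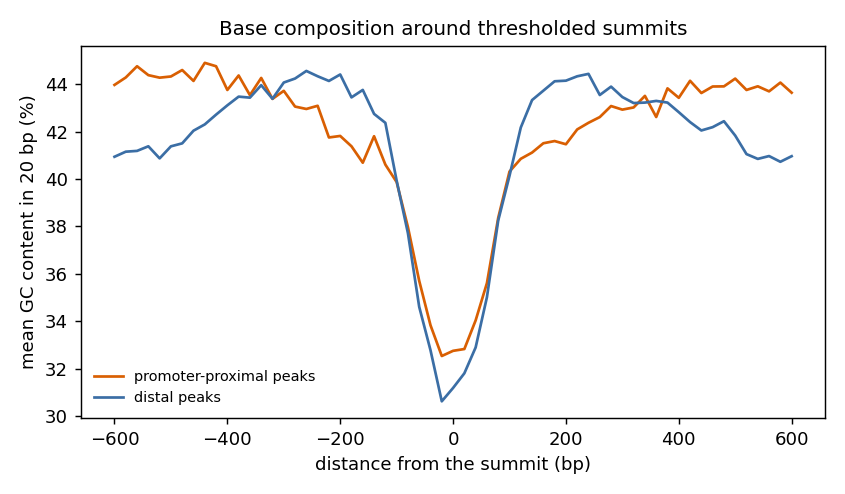
Mean GC content (%, vertical axis) in 20 bp steps by distance from the summit (bp), for promoter-proximal and distal thresholded peaks. Both fall from over 40% at 600 bp to 32.8% (promoter-proximal) and 31.2% (distal) at the summit.

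No E-box was more frequent at summits than in the flanks of the same peaks. Of the 10 E-box sequences, 0 passed as enriched (also 0 at an unadjusted p under 0.05, exact McNemar test, two-sided) and 6 passed as less frequent. CACCTG was within 100 bp of 4.13% of summits and in 8.07% of flanks (ratio 0.511, exact adjusted p = 9.13e-14), and CACGTG in 1.94% and 3.23% (ratio 0.60, exact adjusted p = 0.00097). CAACTG, CAAGTG, CACATG and CAGCTG had ratios of 0.813, 0.837, 0.815 and 0.80 (exact adjusted p = 0.0016 to 0.0046). In the strongest peaks of the replicates CAAGTG (0.857 ± 0.132, SD, n = 3) and CAGCTG (0.919 ± 0.235) were each above their flanks in 1 of 3. CAAATG, CAATTG and CAGATG, at 0.929, 0.928 and 0.941, did not pass. The largest ratio was that of CATATG, in 8.46% of summits and 7.59% of flanks (ratio 1.12, exact adjusted p = 0.17), with 1.18 ± 0.108 (SD, n = 3) in the replicates. When replicate 2 was left out and thresholded peaks were kept only where both other replicates had them, CACCTG alone passed as less frequent, while the other 5 kept ratios of 0.675 to 0.836, near those of the full set, and fell just short of the threshold with fewer peaks (exact adjusted p = 0.053 for each).

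The choice of background decided this result. Against random windows of the same GC content and chromosome arm, CAGCTG (7.40% against 5.29%, ratio 1.40, Fisher's exact adjusted p = 1.07e-06) and CATATG (8.46% against 6.58%, ratio 1.29, adjusted p = 7.15e-05) were more frequent at summits, and none was less frequent past the threshold (2 at an unadjusted p under 0.05, among them CACCTG with a ratio of 0.850). In the replicates these ratios were 1.51 ± 0.0584 and 1.39 ± 0.159 (SD, n = 3), above 1 in 3 of 3.

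No E-box passed as enriched, so CATATG, with the largest ratio against the flanks, was used to compare distal with promoter-proximal peaks. It was more frequent in distal peaks. It was present in 9.49% of 2550 distal peaks (95% Wilson interval 8.41 to 10.7) and in 7.00% of 1786 promoter-proximal ones (5.91 to 8.28), a difference of 2.49 percentage points (Fisher's exact p = 0.0039, two-sided). The replicates gave 10.1% ± 0.597 and 7.08% ± 0.685 (SD, n = 3). Neither class passed against its own flanks, at 8.39% for distal (exact McNemar p = 0.18) and 6.44% for promoter-proximal peaks (p = 0.54). The flanks of the 2 classes thus differed in the same direction, so the difference was not particular to the summits. Against random genomic windows matched to the GC content of each class, a comparison added after seeing the data, CATATG passed in distal peaks (9.49% against 6.89%, ratio 1.38, Fisher's exact adjusted p = 8.0e-05) and not in promoter-proximal ones (ratio 1.11, adjusted p = 0.44). In distal peaks CAGATG (1.21, Fisher's exact adjusted p = 0.044), CACATG (1.19, adjusted p = 0.044) and CAAGTG (1.15, adjusted p = 0.0497) also passed. In promoter-proximal peaks CAGCTG (1.68, Fisher's exact adjusted p = 6.84e-08) and CACGTG (1.74, adjusted p = 0.0057) were more frequent than in these random windows and CAAATG less frequent (0.823, adjusted p = 0.0022). Against the flanks of promoter-proximal peaks there was no such excess. CAGCTG was in 9.52% of summits and 9.52% of flanks, and CACGTG in 2.63% and 3.42% (exact McNemar p = 0.21). Flanks were richer in G and C than summits (44.1% against 33.2% in promoter-proximal peaks, 41.6% against 31.9% in distal ones). The flank comparison thus does not tell whether the surrounding sequence shared these excesses. CAGCTG was distributed the other way, at 5.92% of distal and 9.52% of promoter-proximal peaks (Fisher's exact adjusted p = 0.00012 over the 10 E-boxes).

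Peak strength was not separable by CATATG content. The share was 8.87% in the 868 strongest peaks (95% Wilson interval 7.16 to 10.9) and 7.73% in the 867 weakest (6.13 to 9.70), a difference of 1.14 percentage points (Fisher's exact p = 0.43, two-sided). Promoter-proximal peaks made up 51.4% of the strongest and 40.3% of the weakest of these sets (Fisher's exact p = 3.67e-06). Only the strongest set stood out, since the 3 sets of 867 peaks between them had 39.3%, 36.6% and 38.4%.

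ACACTG and ACAGTG, which share the core CACTG on one strand, led the hexamers at summits with AGTGTA, GTGCAC and AT-rich sequences, and none of these is an E-box. Of all hexamers, counted together with their reverse complements, 496 were more frequent at summits than in the flanks and 1054 less frequent (exact McNemar test, Benjamini-Hochberg adjusted p under 0.05). The 2 sets differed in base composition and overlapped in between. All 36 hexamers without G or C were among the former, and all 36 made only of G and C among the latter. Of the 492 with 2 G or C, 214 were more frequent and 45 less frequent, and of the 640 with 3, 57 and 357. The largest ratio among hexamers present in at least 5% of summits was that of AGTGTA (17.1% of summits, 7.47% of flanks, ratio 2.29, exact adjusted p = 8.09e-41), and the palindrome GTGCAC (8.44% and 3.92%, ratio 2.15), ACACTG (16.7% and 8.0%, ratio 2.09) and ACAGTG (17.4% and 8.46%, ratio 2.05) were also among the leading 10. The other 6 were the AT-rich ATACTA, ATATTA, TTATAA, ATCTTA, AATATT and CTTATA, with ratios of 2.07 to 2.19.

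Against windows of matched GC content, 387 hexamers were more frequent and 414 less frequent at summits. The largest ratios were then those of ACAGTG (2.60, Fisher's exact adjusted p = 1.06e-95, 2.46 ± 0.0503 in the replicates, SD, n = 3), GTGCAC (2.56, 2.23 ± 0.208) and ACACTG (2.47, 2.30 ± 0.117), whereas the AT-rich hexamers of the first comparison had ratios of 1.13 to 1.27. GTGCAC was found in 10.1% of distal and 6.05% of promoter-proximal peaks (Fisher's exact p = 1.65e-06), while ACACTG was in 16.9% and 16.5% (p = 0.71). ACAGTG was in 22.7% of the 868 strongest peaks and 15.3% of the 867 weakest (Fisher's exact p = 0.00011). The 3 sets of 867 peaks between them had 16.8%, 15.8% and 16.3%, so the difference was confined to the strongest peaks.

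**Figure D4:**
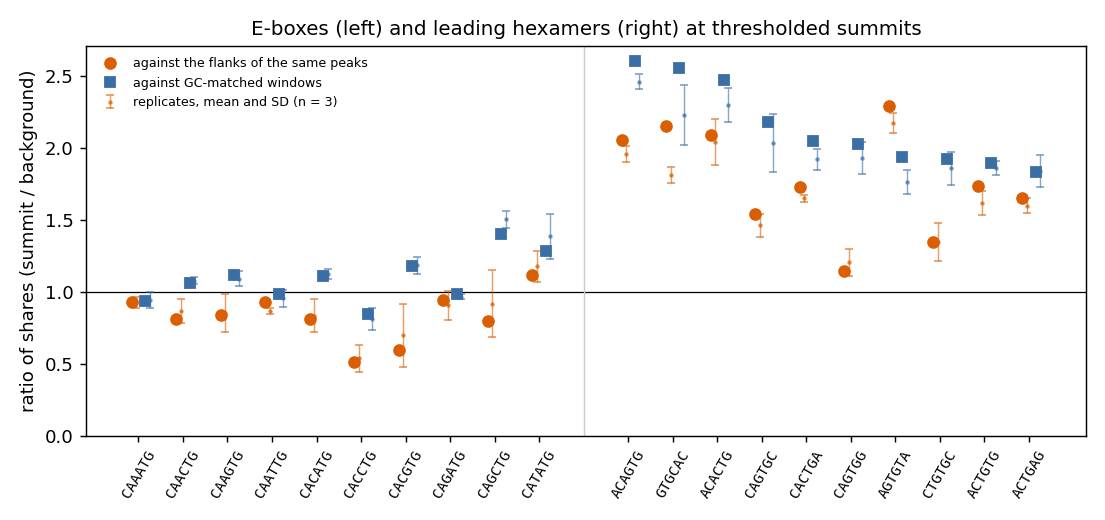
Ratio of the share of thresholded summits with each hexamer to its share in the background, for the 10 E-boxes and for the 10 hexamers with the largest ratio against GC-matched windows. Circles are against the flanks of the same peaks, squares against GC-matched windows, and small points with bars the mean and SD of 3 replicates. E-box ratios run from 0.511 to 1.40, and ACAGTG reaches 2.60.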

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

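Of the values that answer the main comparisons, 61 recomputed ones kept their direction, their side of the threshold or, for counts, their size within 1.5 times, and 9 moved. The promoter share stayed above random placement in each setting run, from 27.3% (6.14% at random) with a TSS window of 200 bp to 52.3% (23.7%) with 1000 bp. The share of peaks found in all replicates was 44.8% at a summit distance of 100 bp and 53.1% at 500 bp. With each replicate left out in turn, the mean correlation of signal ran from 0.52 to 0.76, since a single pair is then left. The difference in CATATG between distal and promoter-proximal peaks passed in each setting, at 1.85 to 4.42 percentage points, and the difference by peak strength in none. Added after seeing the data were the matching of older gene symbols, the split of gene lists by promoter-proximal and distal peaks, the comparison of promoter shares with weaker peaks, the comparison of E-boxes in distal and in promoter-proximal peaks with GC-matched windows, and the overlap of replicates at equal GC content. Also added then was an E-box comparison in the strongest peaks of each replicate, which was run, and in those found in all 3 replicates, which was not run.

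The number of gene lists past the threshold was 3 with gene bodies extended by 1000 bp, 2 with the 2168 strongest peaks, and 8 with unmatched random lists (among them axon guidance and neuronal identity factors), where genes with long surroundings are no longer balanced. Ribosomal proteins passed in each of these and in every setting except distal peaks alone, where 2.17% had a peak (5.71% expected). Lists that moved to the other side of their expected share passed in none of those cases, and the cause was not tested. With gene bodies these were the list of proneural and neurogenin-family bHLH genes (20% with a peak) and neuronal differentiation (29.2%). With peaks within 5000 bp of the TSS they were sensory organ genes (15.4%) and identity factors (15%), with the 2168 strongest peaks neuroblast factors (25%) and the germ line (0%), and with unmatched lists neuroblast factors (33.3%) and neuronal differentiation (25%). With promoter-proximal peaks only they were sensory organ genes (15.4%), neuronal differentiation (16.7%), identity factors (10%), epidermis (13.3%), the germ line (10%) and Hox genes (12.5%), and with distal peaks only neuroblast factors (29.2%), glia (15.4%) and epidermis (13.3%). With a replicate left out the ranges were 25 to 29.2% for neuroblast factors, 23.1 to 30.8% for sensory organ genes, 15.4 to 30.8% for glia, 20 to 20% for epidermis, 0 to 10% for the germ line and 11.1 to 27.8% for the cell cycle.

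E-boxes depended on the background and the window. With GC-matched windows 2 passed as enriched and 0 as less frequent, and the ratios of CAACTG (1.06), CAAGTG (1.12), CACATG (1.11), CACGTG (1.18) and CAGCTG (1.40) turned to above 1, of which CAGCTG passed, while 414 hexamers passed as less frequent. With a summit window of 200 bp to each side 2 E-boxes were less frequent, CACCTG (0.667) and CAATTG (0.878). CAACTG, CAAGTG, CACATG and CACGTG then had ratios of 0.870 to 0.948 without passing, and CAGCTG had 1.06. Leaving out a replicate gave 1 to 6 E-boxes less frequent than the flanks, with fewer peaks in each case. Whichever replicate was left out, the ratios of the 6 E-boxes of the main comparison stayed below 1, and the 5 that did not pass without replicate 2 had 0.675 to 0.836. The absence of read counts means that no value could be set against depth.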

Other observations

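The gene families and the octamers given here, and the tests on ribosomal protein promoters, E-box background, E-box position and replicates, were chosen after the main results were seen, and the test of E-box background after its own values. Among 17 gene families taken by symbol, 2 families of chemosensory receptors were seldom bound. Of 59 odorant receptor genes 3 had a thresholded peak, where matched random lists held 12.7, and of 60 ionotropic receptor genes 2, against 12.2 (permutation test, adjusted p = 0.0045 for each, over the 17 families). Gustatory receptors, at 4 of 60 against 9.70, did not pass (adjusted permutation p = 0.16). The beat, dpr and DIP genes, cell surface proteins of neurons, were also below their random lists, at 5 of 46 against 15.9 (adjusted permutation p = 0.0045), with 10.1% ± 1.26 (SD, n = 3) in the replicates. Tetraspanins were above, at 12 of 34 against 4.84 (ratio 2.48, adjusted permutation p = 0.014), with 33.3% ± 4.49 (SD, n = 3) in the replicates. The random lists drew genes independently, so any family members that lie side by side were treated as independent, which can make these p-values too small. None of the remaining 13 families passed, among them cuticle proteins (9 of 95, against 14.9), cytochrome P450 genes (10 of 85, against 15.9) and nicotinic acetylcholine receptors (1 of 10, against 3.43).

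Most of the octamers with the largest ratios at summits contained the CACTG core. Of 4197 octamers present in at least 1% of summits, the largest ratio to GC-matched windows was that of CACTGAGA, in 3.97% of summits and 0.604% of windows (ratio 6.56, Fisher's exact adjusted p = 1.77e-53, 3.77% ± 0.162 in the replicates, SD, n = 3). It was in 5.29% of distal and 2.07% of promoter-proximal peaks. CAGGGGCG, which lacks that core and was in 1.01% of summits, came next (6.47), followed by CACTGTGC (6.47), CACTGTAC (6.44), ACAGTGGG (6.41), CCACTGTA (6.28) and CAGTGCAC (5.76). GGTCACAC, part of a known core promoter motif of Drosophila, leaned the other way, with 3.86% of promoter-proximal and 0.314% of distal peaks. CAGTGTGA, which holds the CACTG core on one strand, did so as well (2.58% and 0.941%), unlike CACTGAGA. Peaks of ribosomal protein genes differed from other promoter-proximal peaks, with CCGGAA within 100 bp of the summit in 40.4% of 57 against 3.76% of 1731 (Fisher's exact adjusted p = 1.31e-13), and a higher GC content at the summit, 43% against 32.9%.

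Several explanations were tested for the peaks of ribosomal protein genes. An equal recovery of all broadly expressed genes was argued against, since 0 of 3 other families of such genes passed at an unadjusted permutation p under 0.05. Bound were 11 of 73 mitochondrial ribosomal protein genes (expected 8.03), 2 of 48 proteasome genes (expected 6.5) and 13 of 80 genes of the respiratory chain and ATP synthase (expected 12.4). The families were not matched on promoter activity, so a recovery that rises with activity is not excluded. Reads shared between paralogs were argued against as well, since 67.7% of the 65 ribosomal protein genes with no close copy by symbol had a peak (expected 14.6%, permutation p = 0.00020, the smallest possible). Whether CATATG or CAGATG brings the protein there cannot be told apart from chance. Either was in 8.77% of these 57 peaks (95% Wilson interval 3.81 to 18.9). This interval includes the 15.4% of GC-matched windows and the 13.1% of other promoter-proximal peaks. The test did not cover the other E-boxes, among them CAGCTG and CACGTG, so it does not decide the question for E-boxes in general. Open are a recovery of ribosomal protein promoters that does not depend on tap, for which libraries of another GFP-tagged protein were not analysed here, and binding of tap through a partner, neither of which was tested.

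For E-boxes, base composition may account for most of the shortage at summits against flanks, since 0 of the 6 E-boxes below their flanks stayed below GC-matched windows (adjusted p under 0.05), and the ratios of 5 of them rose above 1. CACCTG moved from 0.511 to 0.850 (0.537 ± 0.0955 to 0.810 ± 0.0764 in the replicates, SD, n = 3) and lost its call through the smaller difference and the adjustment (Fisher's exact p = 0.042, adjusted p = 0.098), so a remaining shortage of CACCTG is not excluded. That CATATG reflects binding by tap remains open. In the 50 positions nearest to the summit CATATG was 1.15 times as frequent as in the outer 50, at the 60.2nd percentile of hexamers with 2 G or C, which neither places it at the summit nor excludes that. No biological explanation could be set against a control, as the design has 1 group.

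For the lower overlap of replicate 3, noise at random positions was argued against as the main source, since 42.5% of the 1462 peaks found among the strongest of replicate 3 alone were promoter-proximal (95% Wilson interval 40 to 45.1), near the 40.5% of its peaks found in all 3 and far from the random 13.6%. Peaks found in replicates 1 and 2 alone had still higher promoter shares, 49.5% and 46.7%, so the promoter share does not fall with poor reproducibility, and background recovered at promoters stays open. Shifted summits were argued against as the whole cause, since at a matching distance of 500 bp the overlap with replicate 3 was still 13.1 percentage points below that of replicates 1 and 2 (15.7 at 200 bp). The signal fell with the GC content of the summit in replicates 1 and 2 (Spearman's rho of -0.32 and -0.33 across 3898 peaks) but not in replicate 3 (0.054). When each replicate supplied the same number of strongest peaks from each of 20 strata of summit GC content, the gap in overlap was 9.95 percentage points (95% interval 8.61 to 11.3, bootstrap of 125 genomic blocks), against 15.7 (14.2 to 17.2) without strata, a ratio of 0.635 (0.579 to 0.702). A different GC bias was thus argued against as the whole cause and could account for part of the gap. Peaks of replicate 3 were also narrower (median width 316 bp, against 364 and 376 bp in replicates 1 and 2). Their median signal was 19.8, against 30.6 and 32.1, on scales that differed between lists. Whether either bears on the overlap was not tested. A difference between the embryo collections also stays open and untested.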
